A study of Mus musculus with 2 samples.

How the data were processed

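Single-cell RNA sequencing of 2 liver tumours was analysed. The tumours came from male mice aged 12 months that carry an activating Kras G12D allele switched on in hepatocytes by Cre recombinase under the albumin promoter. Per the labels, both tumours belong to 1 group, and the series holds no control tissue. The labels do not say whether the tumours came from separate mice. Per the labels' protocols, tumours were shelled out of the liver, dissociated with enzymes and loaded on a BD Rhapsody cartridge, which isolates single cells in microwells. Libraries were made with the whole transcriptome kit of that system.

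The deposited values are molecule counts per cell and gene, which the pipeline had corrected for errors in the molecular identifiers, per the file headers. Per the file headers, the counts were made with the BD WTA Rhapsody Analysis Pipeline 1.9.1 on the mouse genome GRCm38 with GENCODE M19. The aligner was not given in the sources used here. All values were whole numbers, and no normalization had been applied. Gene coordinates were taken from GENCODE M21 on the same build.

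Tumour 1 had 2719 cells and 8272141 molecules, and tumour 2 had 172 cells and 1896613 molecules. Cells with under 200 detected genes or over 50% mitochondrial molecules were left out. Scrublet, as built into scanpy 1.11.5, was run in tumours with at least 500 cells and marked 3 doublets in tumour 1. Tumour 2 was too small for it. Of the cells, 1583 were kept in tumour 1 and 142 in tumour 2, with medians of 2479 and 8484.5 molecules.

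Kept cells of both tumours were clustered together with scanpy (Python 3.11.15, leidenalg 0.10.2, igraph 0.11.9). Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 principal components, 15 neighbours and a Leiden resolution of 0.8 were used. All members of the 24 gene lists fixed for testing were kept out of the clustering and of the naming. Clusters were named from 17 fixed marker sets by the share of a set's markers that stood out in the cluster. At least 3 markers and 50% of the set were asked for, in 2 passes. A cluster stayed unnamed if its 10 leading genes held more markers of another class than of its own, or if it was shallow and they held none of its own. Names end in "-like", since they rest on expression alone.

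The class definition was settled after the data had been seen. Clusters made up mostly of tumour 2 cells were clustered a second time, on 500 variable genes and 10 principal components, a setting picked among several trials because the first clustering joined unlike cells of that small tumour. The naming rule went through 3 versions. Without the second clustering, macrophage or monocyte-like and neutrophil-like cells of tumour 2 numbered 2 and 9, so these comparisons depend on it.

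For tests, molecules were summed per tumour and class. The comparisons fixed before the data were examined used edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr, the quasi-likelihood test and the tumour as a block. Classes with at least 10 kept cells in each tumour entered the fit, which were 4 of the classes. Each class was set against the plain mean of the others on the log scale, and Benjamini-Hochberg adjustment was applied with a threshold of 0.05. The replicates are the tumours, not the cells, and the 4 classes of the 2 tumours left 3 residual degrees of freedom. Because classes were defined on the same cells, the tests describe how classes differ and are no independent proof of their identity. With the tumour as a block, an even shift between tumours is removed. The p-values measure how far class differences vary between only these 2 tumours, pooled over the classes in the fit.

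Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over 76 pairs of list and class. Camera with a correlation estimated per list was run beside it. The fry test, which asks whether a list's genes move on balance one way and does not rank them against other genes, was run too.

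A wider fit was added once the cell numbers were known. It takes classes with at least 3 cells in each tumour and the unnamed clusters as 1 more class, which gives 9 classes and 8 residual degrees of freedom. Shares of cells carry exact Clopper-Pearson 95% intervals, and counts scaled to the library total (CPM) carry exact Poisson 95% intervals. Intervals cover counting error only, and a count of 0 allows up to 3 counts. Tumour 1 was set against tumour 2 within a class without a test.

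Genes to name were chosen by a rule fixed before the data were examined. In each comparison the rule took up to 16 list genes and 6 other genes past the threshold, with the same sign in both tumours, by size of the difference. A fixed set of genes, led by Kras and albumin, was read in every class, and the 5 largest ratios each way were taken between tumours. Examples beside a list are the members with the smallest adjusted p. Members that are named outside these rules were chosen after their values were seen.

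The fit was tested on simulated data with known changes. Between 85.4% and 93.9% of genes raised 8-fold were recovered in the planned comparisons, but only 30.4% to 47.8% of those raised 4-fold and 6.82% to 15.4% of those lowered to 0.25 of their level. False calls made up 0% to 4.94% of the calls there, and up to 6.77% in the wider fit. The simulated classes of a tumour shared the same profile apart from the changed genes. Recovery was counted over the changed genes that passed the low-count filter. Genes absent from whole classes, and classes whose makeup differs between tumours, were not simulated, so these rates may not hold for them. The percentile of a list among 10000 matched lists was tested on simulated data too. There it was 100 for a list moved 2-fold and 92.8 for an unmoved one, over 8354 genes.

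Alternatives covered the scaling (DESeq2 1.42.0 size factors), the test (DESeq2 Wald), the low-count filter, the tumour block, each tumour alone, the filter on cells, doublets, the clustering resolution (0.4 and 1.5), the cell minimum (20), naming of single cells, and cells thinned to 1000 molecules. List tests were repeated without the 50 most abundant hepatocyte transcripts. The clustering without its second round, a looser naming of clusters and the alternatives of the wider fit were added after the data had been seen.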

Results

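Molecule counts of single cells were measured in 2 liver tumours of mice with a Kras G12D allele active in hepatocytes, to learn which cells make up such tumours and what they express. Tumour 1 gave 2719 cells with a median of 1368 molecules, and tumour 2 gave 172 cells with a median of 6083.5 molecules. Hemoglobin transcripts made up a mean of 32.5% of a cell's molecules in tumour 1 and 5.78% in tumour 2. Of the cells of tumour 1, 1104 had under 200 genes, and hemoglobin made up over 50% of the molecules in 994 of these. After filtering, 1583 cells with 7165420 molecules remained in tumour 1 and 142 cells with 1853062 molecules in tumour 2.

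Immune cells made up most of the kept cells of tumour 1. Macrophage or monocyte-like cells were the most frequent class among these, with 465 cells or 29.4% (27.1% to 31.7%, exact Clopper-Pearson 95% interval). They were followed by endothelial-like cells with 14.4% (12.7% to 16.2%), T cell-like cells with 13.7% (12.1% to 15.5%) and B cell-like cells with 11.8% (10.3% to 13.5%). Hepatocyte-like cells, the class to which the mutation was directed, made up 9.92% (8.49% to 11.5%), and between 4.86% and 5.55% with no filter on cells, a stricter one, doublets kept or a resolution of 1.5. Neutrophil-like cells made up 8.34%, erythroid-like cells 6.32% and conventional dendritic cell-like cells 3.98%. Plasmacytoid dendritic cell-like, plasma cell-like and stellate or fibroblast-like cells each stayed under 1%, with 15, 9 and 7 cells. Without the filter, erythroid-like cells made up 42.6% and macrophage or monocyte-like cells 20.1% of tumour 1, so the majority and the order above depend on it.

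In tumour 2, the macrophage or monocyte-like class held 38 cells or 26.8% (19.7% to 34.8%) and the neutrophil-like class 18 cells or 12.7% (7.69% to 19.3%). Erythroid-like cells made up 8.45% (4.44% to 14.3%) and T cell-like cells 7.04% (3.43% to 12.6%). Hepatocyte-like, stellate or fibroblast-like and conventional dendritic cell-like cells numbered 6 each, endothelial-like cells 4 and B cell-like cells 1. Another 41 cells or 28.9% (21.6% to 37.1%) lay in 2 clusters that met none of the marker sets. In tumour 1 these 2 clusters held 3 cells or 0.19% (0.0391% to 0.553%). At the main settings no cluster was named as cholangiocytes, NK cells, mast cells or basophils, platelets or megakaryocytes, smooth muscle or mesothelium. By counting error alone, 0 cells allow a share of up to 0.19% in tumour 1 and 2.11% in tumour 2. Such cells inside a cluster of another name would not be counted. With each cell named by its own marker score, each of these classes made up 0.253% to 2.97% of tumour 1. In tumour 2, cholangiocyte-like, smooth muscle-like, mesothelial-like and mast cell or basophil-like cells then made up 2.82% to 7.75% each. NK cell-like and platelet or megakaryocyte-like cells stayed within the exact interval of 0 cells there. Other settings named clusters of these classes: 12 cells of tumour 1 (0.758%) as platelet or megakaryocyte-like at a resolution of 1.5, and 18 cells of tumour 2 (12.7%), from 1 of the unnamed clusters, as cholangiocyte-like with a looser naming. The shares describe the cell suspension, since dissociation, capture and the depth of a cell set what was counted. Without the second clustering, the unnamed clusters would have held 69.0% of tumour 2.

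**Figure D1:**
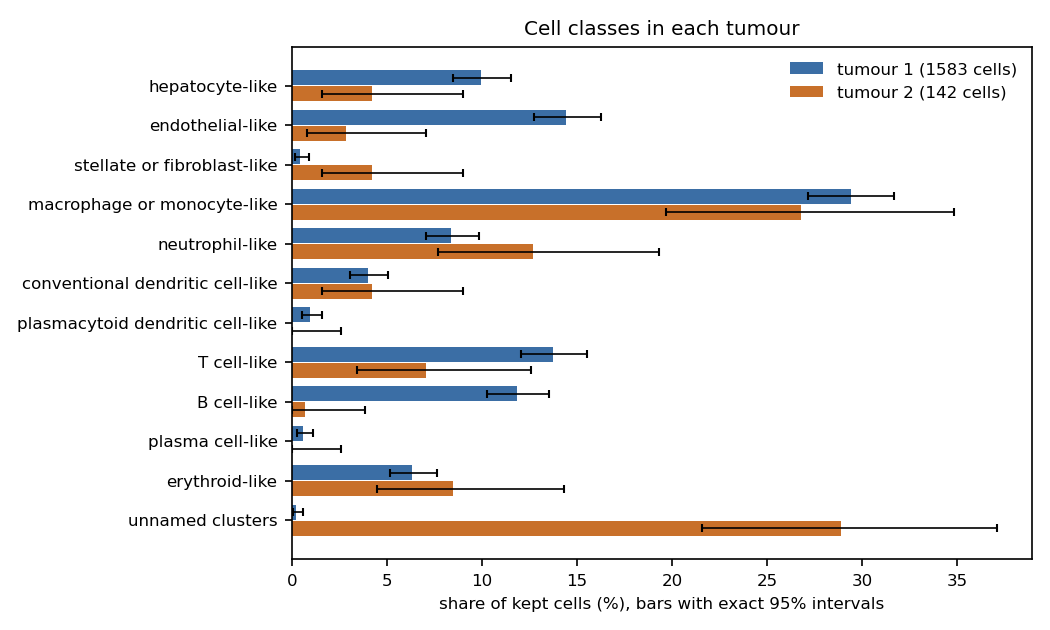
Share of kept cells in each cell class, in percent, with exact 95% intervals, for tumour 1 (1583 cells) and tumour 2 (142 cells). Unnamed clusters hold 28.9% of tumour 2 and 0.19% of tumour 1.

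Kras message was present in most classes. In hepatocyte-like cells it stood at 152 CPM (130.1 to 176, Poisson 95% interval) in tumour 1 and 159 CPM (88.9 to 262) in tumour 2. In the unnamed clusters of tumour 2 it stood at 144 CPM (119.9 to 172). The highest level was in B cell-like cells of tumour 1, with 595 CPM (511 to 688), where the mutation was not directed. The counts do not tell the mutant from the normal allele. On GRCm38, Kras lies on chromosome 6 from 145216699 to 145250239.

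Albumin (Alb, chromosome 5 from 90460897 to 90476602), the main secreted protein of hepatocytes, was read as a gauge of free RNA in other cells. No test told free RNA from doublets or from low expression in those cells. It stood at 32042 CPM in hepatocyte-like cells of tumour 1 and 43125 CPM in those of tumour 2. In the other classes it lay between 125 and 628 CPM in tumour 1 and between 658 and 1101 CPM in tumour 2. The unnamed clusters of tumour 2, at 673 CPM, lay within that range.

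Hepatocyte-like cells carried transcripts known as markers of liver cancer. Without control tissue, these do not tell tumour cells from other hepatocytes. Alpha-fetoprotein (Afp), a fetal liver protein that liver tumours resume, stood at 195 and 106 CPM in hepatocyte-like cells of tumours 1 and 2, against at most 9.88 and 10.4 CPM in the other classes. Glypican 3 (Gpc3), another marker of liver cancer, stood at 318 and 233 CPM there. Gdf15, a stress-induced growth factor, reached 1938 CPM in hepatocyte-like cells of tumour 1 and 148 CPM in those of tumour 2, and 1160 and 572 CPM in macrophage or monocyte-like cells. Osteopontin (Spp1) reached 2618 CPM in hepatocyte-like cells of tumour 1 and 9385 CPM in the unnamed clusters of tumour 2. The other classes of tumour 2, hepatocyte-like cells included, had 885 to 1936 CPM of Spp1. Free RNA could carry such a level, but its origin was not settled.

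Ligands of stroma and immunity were spread over classes. Ctgf, a matrix-inducing factor, stood at 563 and 1419 CPM in stellate or fibroblast-like cells of tumours 1 and 2. Hgf, the hepatocyte growth factor, stood at 157 CPM there in tumour 1 and 20.7 CPM in tumour 2, from 5 and 2 molecules. Cd274, which encodes the checkpoint ligand PD-L1, was highest in neutrophil-like cells of tumour 1 (650.05 CPM) and stood at 308 CPM in those of tumour 2, with 202 and 331 CPM in macrophage or monocyte-like cells. Vegfa, which drives vessel growth, stood at 232 and 234 CPM in neutrophil-like cells. Tgfb1 stood at 88.5 and 178 CPM in T cell-like cells. Trem2, a lipid receptor of macrophages, stood at 283 and 174 CPM in macrophage or monocyte-like cells. Hras stood at 31.9 and 138 CPM in hepatocyte-like cells, and Nras at 87.1 and 63.5 CPM.

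**Figure D2:**
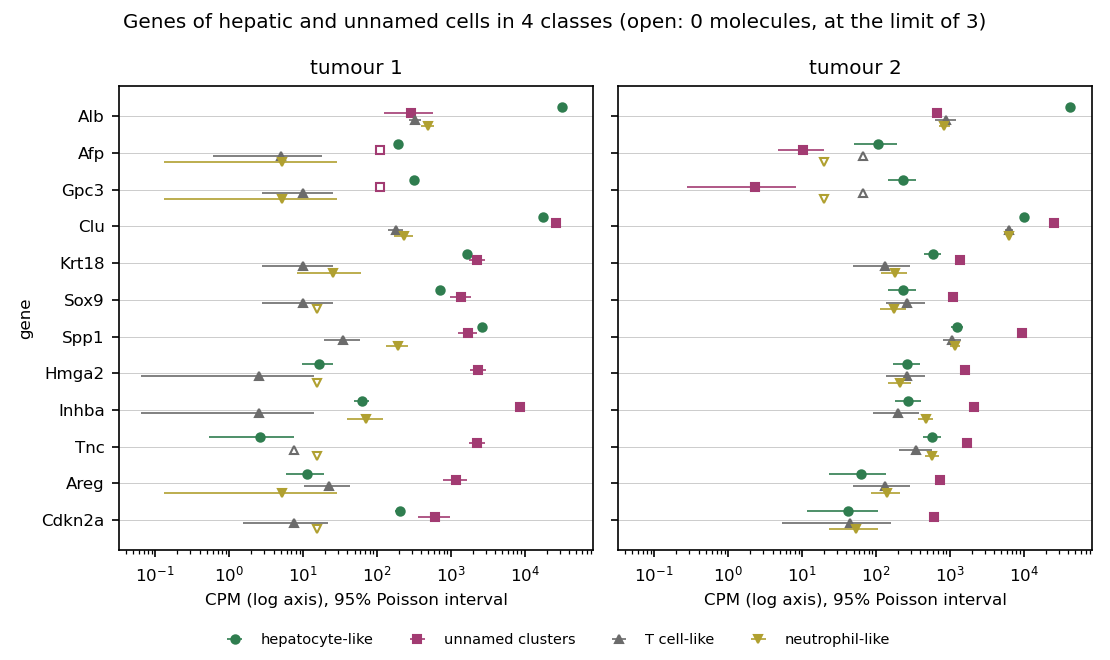
Level of 12 genes in CPM on a log axis, with Poisson 95% intervals, in 4 cell classes of each tumour, with open symbols for 0 molecules. Hmga2 stands at 2373 and 1625 CPM in the unnamed clusters of tumours 1 and 2, and T cell-like and neutrophil-like cells carry 6327 and 6338 CPM of Clu in tumour 2 but 182 and 232 CPM in tumour 1.

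T cell-like cells of these tumours carried genes of killing and of checkpoint control. In the comparison with the mean of macrophage or monocyte-like, neutrophil-like and erythroid-like cells, the protease granzyme B (Gzmb) was higher by a log2 difference of 10.22 (SE 1.26), at 1762 and 88.8 CPM in tumours 1 and 2. Pdcd1, the checkpoint receptor PD-1, was higher by 9.14 (SE 1.18), at 240.2 and 511 CPM. Ctla4, a checkpoint receptor that binds the ligands of CD28, was higher too, at 187 and 488 CPM, and Il2rb, a receptor chain for interleukins, was higher by 6.57 (SE 0.77). Tigit was at least 114-fold higher, with no molecule in the other classes.

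Of 15 tested genes of the T cell effector list, 13 were higher and 1 lower in T cell-like cells, among them Il2rb, Trdc, Cxcr6 and Gzmb, and 13 and 1 when adjusted over the list alone. The list was higher by camera (adjusted p = 3.97e-14), but adjusted p = 0.532 with an estimated correlation. Of 15 checkpoint genes, 7 were higher and none lower, among them Pdcd1, Icos, Ctla4 and Tox, and 7 when adjusted over the list alone (camera adjusted p = 0.000373, and adjusted p = 0.532 with an estimated correlation). Of 13 genes of MHC class I, which shows peptides to killer T cells, 4 were higher (H2-Q6, H2-Q7, Nlrc5 and H2-Q4), and 6 when adjusted over the list alone. Camera gave an adjusted p of 7.20e-05 for that list, with adjusted p = 0.532 with an estimated correlation. Of the chemokines, 2 were higher (Ccl5 and Xcl1) and 7 lower out of 14.

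Lists of phagocytes were lower in T cell-like cells. This held for 7 of 21 genes of tumour-associated macrophages, among them Gpnmb and Cd63, for 6 of 9 genes of MHC class II and for 4 of 11 Kupffer cell genes. When adjusted over the list alone, 13, 8 and 9 were lower. Camera gave adjusted p of 1.29e-05, 6.28e-05 and 0.000487 for these, with adjusted p of 0.532, 0.558 and 0.532 with an estimated correlation. The lists of chemokines, matrix (2 of 19 members lower), sinusoidal endothelium (1 of 6), growth factors (none of 15) and glycolysis (1 of 16) were lower too, with camera adjusted p of 0.00469 to 0.0419 and adjusted p of 0.532 to 0.579 with an estimated correlation. The chemokine Cxcl3 had no molecule in T cell-like cells, against 392 CPM in neutrophil-like cells of tumour 1.

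Genes outside the lists that were higher in T cell-like cells included Gimap4, a GTPase of lymphocytes (6.97, SE 0.89), the transcription factor Ets1 (4.08, SE 0.68), the glucocorticoid receptor Nr3c1 (3.07, SE 0.68) and the interferon gamma receptor Ifngr1 (2.71, SE 0.66). In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 198 genes higher and 232 lower of 4502 tested, and 425 of these 430 differed the same way in both tumours. Tumour 2 had 10 such cells, and without the tumour block 98 genes were lower.

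Single genes per cell described the T cell-like class of tumour 1, which had a median of 1648 molecules per cell. Of 217 cells, 46.5% had a molecule of Cd8a and 11.1% of Cd4. In the same tumour 25.3% had Pdcd1, 39.6% Icos, 46.1% Gzmb and 34.1% Il7r. Of 187 B cell-like cells, with a median of 1419 molecules, none had Cd8a, Cd4, Pdcd1 or Icos, 1.60% had Gzmb and 0.535% Il7r. In tumour 2, 5 of 10 cells had Trdc, the constant chain of the gamma delta receptor, and 2 of 10 had Cd8a. In tumour 1, 6.45% had Trdc. No test was run between the tumours.

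Pooled over its clusters, the macrophage or monocyte-like class carried genes of resident Kupffer cells and of lipid-handling tumour macrophages. In tumour 1 the Kupffer cell genes lay in 1 of its 2 large clusters, with Vsig4 at 599 against 4.08 CPM. In the comparison with T cell-like, neutrophil-like and erythroid-like cells, the Kupffer cell lectin Clec4f was higher by a log2 difference of 5.93 (SE 1.14), at 319 and 15.4 CPM in tumours 1 and 2. In tumour 2 that level came from 7 molecules and lay below the 53.7 CPM of erythroid-like cells, and the differences within tumours 1 and 2 were 5.29 and 0.98. The complement receptor Vsig4 was higher by 4.88 (SE 0.79), the mannose receptor Mrc1 by 4.89 (SE 0.73) and lipoprotein lipase (Lpl) by 4.78 (SE 0.73). Gpnmb, a glycoprotein of lipid-laden macrophages, was higher by 4.32 (SE 0.77), at 1650.1 and 94.9 CPM. The growth factor Igf1 was higher by 6.50 (SE 1.02), at 386 and 258 CPM.

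All 11 tested Kupffer cell genes were higher (Cd5l, Vsig4, Clec4f and Slc40a1 first), and 11 when adjusted over the list alone. Of 21 genes of tumour-associated macrophages 10 were higher, among them Mmp12, Lpl, Gpnmb and Trem2, with 15 higher and 1 lower when adjusted over the list alone. Camera gave adjusted p of 2.66e-10 and 5.29e-08 for these, and adjusted p = 0.532 with an estimated correlation for both. Of 9 genes of MHC class II, 8 were higher, among them Ctss, H2-DMb1, H2-DMa and Cd74 (8 when adjusted over the list alone). Of 14 chemokines, 8 were higher, among them the monocyte attractants Ccl2, Ccl7 and Ccl8 (9 higher and 1 lower when adjusted over the list alone). Their camera adjusted p were 7.57e-07 and 0.000109, and adjusted p = 0.532 with an estimated correlation for both.

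Scavenger receptors of the sinusoidal list that macrophages share, Mrc1, Stab1 and Fcgr2b, were higher, with 4 of 6 members called (camera adjusted p = 6.28e-05, and adjusted p = 0.532 with an estimated correlation). Growth factors followed with 4 of 15, which were Igf1, Gdf15, Il6 and Hbegf (camera adjusted p = 0.0021, and adjusted p = 0.532 with an estimated correlation). Proliferation genes were lower, with 5 of 13 members including Nusap1 and Ube2c (camera adjusted p = 2.21e-05, and adjusted p = 0.558 with an estimated correlation). Effector genes of T cells were lower too, with 3 lower and 1 higher of 15 (camera adjusted p = 4.17e-05, and adjusted p = 0.532 with an estimated correlation).

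The metalloproteases Mmp12, Mmp13 and Mmp14, which degrade matrix, were higher in macrophage or monocyte-like cells by 4.78 (SE 0.70), 6.13 (SE 1.07) and 5.49 (SE 0.98). The matrix list was not called, with 4 of 19 members higher (camera adjusted p = 0.436). Outside the lists, the efferocytosis receptor Mertk was higher by 6.55 (SE 1.07), and Lilra5, an activating immune receptor, was at least 34.8-fold higher, with no molecule in the other classes. The quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment called 271 genes higher and 44 lower, and 314 of 315 differed the same way in both tumours. DESeq2's Wald test gave 141 and 88, and without the tumour block 133 and 7 were called.

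Neutrophil-like cells carried Cxcl2, an attractant of neutrophils, while the chemokine list was not called (4 of 14 members higher and 1 lower, camera adjusted p = 0.795). The makeup of the class differed between tumours. In tumour 2, 9 of 18 cells lay in a cluster rich in granule proteins, which held no cell of tumour 1. They had a median of 5825 molecules, against 2332.5 and 2627 in the other clusters, and held most molecules of the class there. In the comparison with T cell-like, macrophage or monocyte-like and erythroid-like cells, Cxcl2 was higher by a log2 difference of 3.83 (SE 0.83), at 22561 and 4651 CPM in tumours 1 and 2. Macrophage or monocyte-like cells of tumour 2 had 4919 CPM of it. Lcn2, an iron-binding defence protein, was higher by 5.73 (SE 0.76), at 2466 and 9972 CPM, and the homing receptor Sell by 3.63 (SE 0.71). Slc16a3, which exports lactate, was higher by 4.63 (SE 0.74), and Bnip3, induced by low oxygen, by 4.41 (SE 1.38). In tumour 2, Bnip3 stood at 20.1 CPM from 3 molecules, below the 79.4 CPM of macrophage or monocyte-like cells.

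Slc16a3 and Bnip3 were the 2 genes of 16 called in the glycolysis and hypoxia list, and 2 when adjusted over the list alone (camera adjusted p = 0.00165, and adjusted p = 0.532 with an estimated correlation). The checkpoint ligand Pdcd1lg2 was higher by 4.60 (SE 1.29), and Fosl1, a transcription factor downstream of MAPK signalling, by 3.39 (SE 0.88). The matrix protein thrombospondin 1 (Thbs1) was higher by 3.30 (SE 0.71), the complement receptor C5ar1 by 3.75 (SE 0.73) and the glycogen phosphorylase Pygl by 4.05 (SE 0.69). The chemokine receptor Ccr2 was lower, with a log2 difference of -4.50 (SE 1.05), and the chemokine Ccl5 with -3.68 (SE 1.09). The lists of MHC class II, with no single member called of 9, and of T cell effectors, with 1 higher and 1 lower of 15, were lower (camera adjusted p = 0.0262 and 0.0415, and adjusted p of 0.758 and 0.532 with an estimated correlation). The first had a median of -2.51 in tumour 1 and 0.19 in tumour 2. The quasi-likelihood test with Benjamini-Hochberg adjustment in edgeR called 318 genes higher and 41 lower, with 346 of 359 alike in sign. Genes lower were 19 without the tumour block, 15 without the low-count filter and 94 with cells thinned to 1000 molecules.

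Erythroid-like cells carried cell cycle genes in tumour 1, as dividing red cell precursors do. The comparison with T cell-like, macrophage or monocyte-like and neutrophil-like cells gave 6 of 13 proliferation genes as higher, among them Ube2c (5.27, SE 0.75) and Nusap1 (4.88, SE 0.78), and 9 when adjusted over the list alone. Camera gave an adjusted p of 2.75e-07 for the list, with adjusted p = 0.532 with an estimated correlation. The tumours differed here. The median log2 difference of the list, with a prior count of 2, was 4.61 in tumour 1 and -0.82 in tumour 2, which had 12 such cells.

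The antiviral gene Rsad2 was higher in erythroid-like cells by 6.02 (SE 0.78), at 1991 and 806 CPM, and 3 of 10 interferon genes were called (Rsad2, Isg15 and Igtp). That list had a camera adjusted p of 0.0408, and adjusted p = 0.558 with an estimated correlation, with medians of 1.14 and -1.99 in the 2 tumours. The lists of MHC class II (none of 9 called) and of matrix (Col4a1 of 19 called) were higher by camera (adjusted p = 0.00162 and 0.0247, and adjusted p of 0.594 and 0.532 with an estimated correlation), though the medians in tumour 2 were -0.59 and 0.03. The matrix list turned to lower in the wider fit (adjusted p = 0.857). Outside the lists, the peroxidase Gpx1, which protects red cells from oxidants, was higher by 4.68 (SE 0.77), and Slc25a39, which carries glutathione into mitochondria, by 5.30 (SE 0.73). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 185 genes higher and 2 lower, and 156 of 187 differed alike in both tumours.

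In these 4 comparisons, 26 of 76 pairs of list and class were called by camera. None was called with an estimated correlation, and fry called 4, of which 3 were among the 26, so the calls by list rest on the preset correlation. A mean over classes on the log scale falls where a class has few or no molecules, so large differences mark genes nearly absent from some of the other classes.

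The wider fit, added after the cell numbers were known, set hepatocyte-like cells against 8 other classes. They carried the metabolic genes of both zones of the liver lobule. Hsd17b13, a lipid droplet enzyme of periportal cells, was higher by a log2 difference of 7.98 (SE 0.55), at 843 and 805 CPM, and Cps1, the entry enzyme of the urea cycle, by 6.38 (SE 0.62). Cyp3a11 and Cyp2a5, pericentral enzymes of drug metabolism, were higher by 6.80 (SE 0.90) and 6.72 (SE 0.90). The oncofetal genes Gpc3 and Afp were higher by 7.25 (SE 0.66) and 6.41 (SE 0.77), and Ly6d, a surface protein, by 5.78 (SE 0.48). Scd1, the desaturase of fat synthesis, was higher by 5.14 (SE 0.43), at 2437 and 3293 CPM, and Pcsk9, which lowers LDL receptors, by 6.40 (SE 0.99).

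Of 9 periportal genes, 8 were higher, and of 7 pericentral genes, 5 (8 and 5 when adjusted over the list alone). Camera gave adjusted p of 1.22e-10 and 0.000152 for these, with adjusted p of 0.0802 and 0.151 with an estimated correlation. Of 6 genes of bile acid and cholesterol metabolism 4 were higher, of 9 oncofetal genes 6, and of 11 lipid genes 6 (6 and 6 higher, then 8 higher and 1 lower, when adjusted over the list alone). Their camera adjusted p were 0.000121, 0.000396 and 0.0103, with adjusted p of 0.0802, 0.203 and 0.15 with an estimated correlation. Of 15 genes of p53 and senescence, 10 were higher and 1 lower, among them Trp53inp1, Cdkn2a, Gdf15 and Cdkn2b (camera adjusted p = 0.0202, and adjusted p = 0.746 with an estimated correlation), with a median of 2.68 in tumour 1 but 0.11 in tumour 2. At a resolution of 1.5, an albumin-high cluster held 77 cells of tumour 1 and 5 of tumour 2. An albumin-poor one held 82 and 1, and in tumour 1 all 14 genes of that list stood higher in it. This makeup could account for the gap, which was not tested.

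Proliferation genes were lower in hepatocyte-like cells, with 8 of 17 members including Top2a and Nusap1 (camera adjusted p = 0.000104, and adjusted p = 0.715 with an estimated correlation). The list of endoplasmic reticulum and oxidative stress was higher with 7 of 19 members, led by Atf5 and the metallothioneins Mt1 and Mt2 (camera adjusted p = 0.0288, and adjusted p = 0.715 with an estimated correlation). With the quasi-likelihood test of edgeR and Benjamini-Hochberg adjustment, the calls were 848 genes higher and 241 lower of 6406. Tumour 2 had 6 of these cells, and with cells thinned to 1000 molecules 161 and 28 were called.

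The unnamed clusters carried growth factors, genes of Ras output and a fetal architectural factor. Hmga2, a chromatin protein of fetal tissue and a member of the Ras output list (chromosome 10 from 120361275 to 120476469), was higher than in the mean of the other classes by a log2 difference of 6.58 (SE 0.57). It stood at 2373 CPM in the 3 cells of tumour 1 and at 1625 CPM in the 41 cells of tumour 2. Inhba, a subunit of activin, was higher by 6.84 (SE 0.52), and tenascin C (Tnc), a matrix protein of wounds and tumours, by 8.33 (SE 0.71). Ereg and Btc, ligands of the EGF receptor, were higher by 5.91 (SE 0.91) and 4.36 (SE 0.69). The cell cycle inhibitor Cdkn2a was higher by 4.69 (SE 0.63), at 621 and 612 CPM.

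Of 23 growth factor genes, 12 were higher in the unnamed clusters, among them Inhba, Bmp2, Areg and Cyr61 (13 higher and 1 lower when adjusted over the list alone), a call that held with an estimated correlation (camera adjusted p = 3.86e-13, and adjusted p = 0.0452 with an estimated correlation). Of 16 Ras and MAPK output genes, 7 were higher, among them Hmga2, Emp1, Ier3 and Ccnd1, and 9 when adjusted over the list alone (camera adjusted p = 2.19e-08, and adjusted p = 0.0802 with an estimated correlation). Of 15 genes of p53 and senescence, 7 were higher, among them Cdkn2a, Phlda3, Eda2r and Cdkn2b (camera adjusted p = 9.93e-08, and adjusted p = 0.324 with an estimated correlation). The lists of matrix, with 8 of 36 higher, and of stellate cell activation, with 5 of 13, followed (camera adjusted p = 0.000799 and 0.00986, and adjusted p of 0.698 and 0.144 with an estimated correlation), and both had negative medians of -0.66 and -0.65 in the 3 cells of tumour 1.

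Genes of antigen display were lower as lists in the unnamed clusters. For MHC class I no single gene of 13 was called (camera adjusted p = 3.67e-05, and adjusted p = 0.169 with an estimated correlation), and for MHC class II Cd74 alone of 11 (camera adjusted p = 0.000693, and adjusted p = 0.698 with an estimated correlation). Of 11 interferon genes, Isg15, Gbp7 and Irf7 were lower, with 2, 4 and 2 molecules among 41 cells of tumour 2 (camera adjusted p = 0.00137, and adjusted p = 0.366 with an estimated correlation). Of 17 proliferation genes, 2 were lower (camera adjusted p = 0.000359, and adjusted p = 0.718 with an estimated correlation). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 298 genes higher and 25 lower. Without the tumour block 9 were lower, and with cells thinned to 1000 molecules, from a median of 20002 in those of tumour 2, the calls were 60 and 1.

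Set against hepatocyte-like cells, the unnamed clusters had fewer transcripts of hepatocyte metabolism. Of 9 periportal genes 7 and of 7 pericentral genes 5 were lower, both calls that held with an estimated correlation (camera adjusted p = 1.71e-11 and 2.26e-05, and adjusted p = 0.0404 with an estimated correlation for each). Gc, a plasma protein of hepatocytes chosen after its values were seen, was present at 2568 CPM in the unnamed clusters of tumour 2, with a log2 difference of -3.23 (SE 0.82). The pericentral enzyme Cyp2e1 had no molecule there, at least 21.2-fold lower, and the periportal Hsd17b13 differed by -7.64 (SE 1.15). Of 9 oncofetal genes, 4 were lower and 1 higher, and Gpc3 had 2 molecules in the unnamed clusters of tumour 2. Hmga2, Inhba and Tnc were higher than in hepatocyte-like cells by 5.67 (SE 0.95), 5.62 (SE 0.94) and 7.84 (SE 1.11), and so were Bmp2 by 5.33 (SE 0.98) and the plasminogen activator Plat by 3.93 (SE 0.90). Keratin genes of epithelium, chosen after the values were seen, were present in both classes, with Krt18 at 2299.9 and 1393 CPM in the unnamed clusters and at 1657 and 593 CPM in hepatocyte-like cells, against 73.1 to 234 CPM in the other classes of tumour 2. With the quasi-likelihood test of edgeR and Benjamini-Hochberg adjustment, the calls were 84 genes higher and 288 lower.

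Pooled over its 2 clusters, the endothelial-like class carried genes of both capillaries and sinusoids. The sinusoidal cluster held 174 cells of tumour 1 and only 1 of tumour 2, and the other cluster 54 and 3. All 14 tested capillary genes were higher, among them Plvap, Selp, Cd34 and Esm1 (14 when adjusted over the list alone, camera adjusted p = 9.64e-23, and adjusted p = 0.0331 with an estimated correlation). All 13 sinusoidal genes were higher too, led by Clec4g, Stab2, Gpr182 and Dnase1l3 (camera adjusted p = 1.71e-19, and adjusted p = 0.149 with an estimated correlation). The adhesion molecule Selp differed by 6.04 (SE 0.54), at 667 and 658 CPM, and the scavenger receptor Stab2 by 6.83 (SE 0.64). Fabp4 and Cd36, which carry fatty acids, were higher by 5.13 (SE 0.48) and 4.06 (SE 0.47), and basement membrane collagen Col4a2 by 4.28 (SE 0.46). Of 36 matrix genes, 13 were higher and 2 lower (camera adjusted p = 0.0111, and adjusted p = 0.746 with an estimated correlation). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 629 genes higher and 31 lower, with 4 cells behind tumour 2.

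Stellate or fibroblast-like cells carried matrix and contractile genes. Of 36 matrix genes, 32 were higher, among them the collagens Col14a1, Col6a2, Col15a1 and Col6a1 (32 when adjusted over the list alone), and of 13 genes of stellate cell activation 9 were higher, among them Acta2, Tpm2, Cald1 and Ltbp2 (12 when adjusted over the list alone). Both calls held with an estimated correlation (camera adjusted p = 1.13e-58 and 8.34e-15, and adjusted p of 0.00994 and 0.00579 with an estimated correlation). Periostin (Postn) differed by 8.09 (SE 0.74), at 93.9 and 1377 CPM, and Ctgf by 4.43 (SE 0.60). Of 17 proliferation genes, 7 were higher, among them Top2a, Cdk1, Ccna2 and Mki67 (camera adjusted p = 1.32e-05, and adjusted p = 0.698 with an estimated correlation). With the quasi-likelihood test of edgeR and Benjamini-Hochberg adjustment, the calls were 381 genes higher and 39 lower, from 7 and 6 cells.

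Conventional dendritic cell-like cells carried the machinery of antigen presentation. All 11 tested genes of MHC class II were higher, led by H2-Ob, H2-DMb2, H2-Eb1 and Cd74 (11 when adjusted over the list alone, camera adjusted p = 1.49e-23, and adjusted p = 0.0452 with an estimated correlation). The chemokine Ccl22, which attracts regulatory T cells, differed by 7.21 (SE 0.52), at 682 and 1223 CPM, and the inhibitory receptors Btla and Havcr2 by 4.19 (SE 0.68) and 3.37 (SE 0.58). Of 17 proliferation genes, 5 were higher (camera adjusted p = 6.19e-05, and adjusted p = 0.698 with an estimated correlation), and of 13 MHC class I genes 2 (camera adjusted p = 0.0196, and adjusted p = 0.664 with an estimated correlation). The interferon gene Iigp1 had no molecule in these cells, at least 25.6-fold lower than in the others. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 302 genes higher and 26 lower.

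Within tumour 1, the macrophage or monocyte-like cells fell at the main resolution into a Kupffer cell part of 222 cells and a monocyte part of 243 cells, compared without a test. Their medians were 7332 and 4609 molecules per cell. At the highest resolution used, clusters of 34, 123 and 64 cells of tumour 1 had Fcna, Atp6v0d2 and C1qa among their leading genes. These genes also led the Kupffer cell part, which may therefore mix cell states. The same holds for the monocyte part, since clusters of 101 and 143 cells of tumour 1 had its leading genes Clec4e and Tppp3 among theirs. The cluster of 64 cells had medians of 1254.5 molecules and 13.6% mitochondrial molecules. The values below are for each part as a whole. The list of tumour-associated macrophages and monocytes went both ways, so the name of the monocyte part does not rest on it. Of its 23 genes, 10 stood higher and 13 lower in the Kupffer cell part (median log2 ratio -0.27, percentile 19.8). All 12 Kupffer cell genes stood higher in the Kupffer cell part, with a median log2 ratio of 4.89. The 15 proliferation genes did so too, with a median of 2.31, and both medians lay at percentile 100 of 10000 matched lists. Interferon genes stood higher in 17 of 21 (median 0.85, percentile 99.9), among them Ifit3 and Rtp4. Genes of glycolysis and hypoxia stood lower in 17 of 19 (median -0.76, percentile 0). Genes of dissociation stress moved with the split, higher in 17 of 21 in the Kupffer cell part (median 0.65), as with Egr1 (642 against 112 CPM) and Jun (1110.5 against 246 CPM). The attractant Ccl8 stood at 350.4 against 12.2 CPM and the desaturase Scd1 at 333 against 35.1 CPM. Growth factors stood higher in the Kupffer cell part in 11 of 17 (median 1.30, percentile 100) and matrix genes in 7 of 11 (median 0.16, percentile 70.2). The monocyte part had more of some members, such as fibronectin (Fn1, 793 against 17.1 CPM), Thbs1 (1915 against 109 CPM) and Inhba (118 against 2.21 CPM), and of Chil3 (520.5 against 3.32 CPM).

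Endothelial-like cells of tumour 1 also had 2 parts. In the sinusoidal part of 174 cells all 14 sinusoidal genes stood higher than in the other 54 cells (median log2 ratio 4.18, percentile 100), as with Dnase1l3 (2764 against 33.6 CPM) and Clec4g (2763 against 33.6 CPM). The growth factors Rspo3 (92.6 CPM), Hgf (67.0 CPM) and Bmp2 (747 CPM), through which sinusoids act on hepatocytes, were read there. The other part had more Cd34 (1242 against 264 CPM) and Col15a1 (772 against 39.4 CPM). Genes of dissociation stress moved with this split too, higher in the other part in 19 of 21 (median log2 ratio -1.13 for the sinusoidal part, percentile 0), as with Hspb1 (1857 against 176 CPM). Kupffer cell genes stood higher in all 12 members in the sinusoidal part (median 3.41), where C1qa stood at 311 against 11.2 CPM, and at 2125 CPM in the Kupffer cell part.

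Hepatocyte-like cells of tumour 1 formed 1 cluster at the main resolution, and its 157 cells fell into 2 clusters at a resolution of 1.5. The second of these had 11 of 12 hepatocyte markers but stayed unnamed, since its 10 leading genes held none of them and 2 cholangiocyte markers (Sox9 and Tm4sf4). The albumin-high part of 77 cells had 54030 CPM of Alb. The other part of 82 cells, of which 80 were of the hepatocyte-like class and 2 were not, had 6887 CPM. All 11 pericentral genes (median log2 ratio 3.06, percentile 100) and 11 of 13 periportal genes (median 1.57) stood higher in the albumin-high part, with Cyp3a11 at 237 against 5.24 CPM and Arg1 at 664 against 21.0 CPM. In the other part all 17 Ras and MAPK output genes (median -2.22, percentile 0), all 14 genes of p53 and senescence (median -2.11) and 14 of 15 growth factors (median -2.32) stood higher. These included Ier3 (630.4 against 76.1 CPM), Cdkn1a (2260 against 282 CPM), Mdm2 (756 against 68.0 CPM) and Cyr61 (1449 against 185 CPM). Chosen after the values were seen, clusterin (Clu) stood at 26010 against 9784 CPM, Sox9 at 1256 against 206 CPM and Krt8 at 2204 against 421 CPM in that part. All 8 Kupffer cell genes stood higher in it as well (median -2.57), with C1qa at 114 against 19.4 CPM. All 21 genes of dissociation stress stood higher in it too (median -1.90), as did mitochondrial molecules, with medians of 7.96% against 3.53% of a cell.

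**Figure D3:**
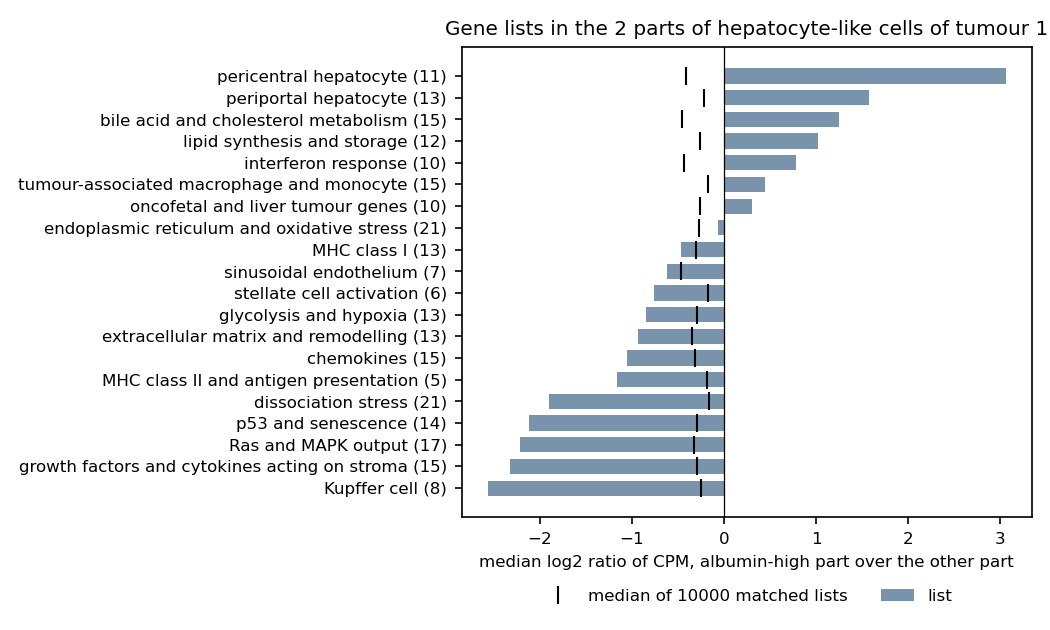
Median log2 ratio of CPM per gene list between the albumin-high part (77 cells) and the other part (82 cells, 80 of them of the hepatocyte-like class) in tumour 1. Ticks stand at the median of 10000 matched lists, with the number of genes in brackets. Pericentral genes lie at 3.06, Ras and MAPK output at -2.22 and dissociation stress at -1.90.

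Tumour 1 and tumour 2 were set side by side within each class, 1 tumour on each side, so no difference has a replicate check. T cell-like cells formed 1 cluster at the main resolution and 2 at a resolution of 1.5. There 98 cells of tumour 1 and none of tumour 2 lay in a cluster with Cd8a, Cd8b1 and Gzma among its leading genes, and 119 and 10 in the other. T cell-like cells of tumour 1 had 19.8-fold as much Gzmb (7.72 to 73.0), at 1762 against 88.8 CPM, and Gzma stood at 1014 CPM against 22.2 CPM, from 1 molecule (a ratio of 45.7, interval 8.15 to 1808). Klrb1b, a receptor of innate lymphocytes, was 7.36-fold higher in tumour 2, at 577 against 78.4 CPM, while the other classes had 32.5 and 32.6 CPM. Clu, Spp1 and Igfbp4 were 34.8-fold, 30.7-fold and 17.9-fold higher in T cell-like cells of tumour 2. These 3 transcripts stood at 25575, 9385 and 4753 CPM in the unnamed clusters of that tumour.

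Macrophage or monocyte-like cells (2 clusters in tumour 1, holding 1 cell each of tumour 2, and 2 others in tumour 2) of tumour 1 had 20.7-fold as much Clec4f (9.99 to 51.5), and Marco stood at 166 against 2.21 CPM, from 1 molecule (75.1, interval 13.4 to 2972). Tnc was at least 471-fold higher in those of tumour 2, at 466 CPM, but stood at 1719 CPM in the unnamed clusters. In tumour 2, 9 of 18 neutrophil-like cells lay in a cluster rich in granule proteins, with most of the molecules and no cell of tumour 1. Neutrophil-like cells of tumour 2 had 20318 CPM of Ngp against 144 CPM. Camp, Chil3 and Prg2 had no molecule in those of tumour 1 and were at least 360.2-fold, 226-fold and 533-fold higher in tumour 2. The growth factor Csf1 was 30.2-fold higher in neutrophil-like cells of tumour 1 (15.1 to 70.5), at 1615 against 53.5 CPM, and Hmox1, which breaks down heme, 21.1-fold (10.5 to 49.5). Erythroid-like cells (1 cluster) of tumour 1 had 590.4 CPM of Mki67 against 53.7 CPM, from 1 molecule (11.0, interval 1.94 to 438), and those of tumour 2 had 21.8-fold as much Clu (16.7 to 28.5).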

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

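The tests without the second clustering, with a looser naming of clusters, without the granule cluster and all those on the wider fit were chosen only after the results were seen. Of 933 repeats of named genes on both tumours in the planned comparisons, 858 kept direction and side of the threshold and 75 kept the direction only. In the wider fit these were 500 and 84 of 584. Genes that were not tested in a repeat are not counted. Of 80 named genes of the planned comparisons, 55 were tested with thinned cells and 25 without the second clustering. In the wider fit, thinning left 56 of 132. From 1 tumour alone, 98 of 160 and 175 of 264 differences moved by more than the spread. Single lists kept their side in 304 of 387 repeats of the planned comparisons and in 173 of 266 of the wider fit. The one list that reversed was that of matrix genes in erythroid-like cells, with an adjusted p of 0.857 in the wider fit. All 40 ratios between tumours stayed on their side with the abundant hepatocyte transcripts left out of the totals. That outcome was set in advance, since it rescales all genes of a class alike and the ratios were picked as the largest. Of 286 repeated shares, classes with 0 cells included, 234 stayed within their interval. Where nothing else is said, the cause was not tested.

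Without a filter on cells, erythroid-like cells made up 42.6% of tumour 1, and most other shares were lower. They were 5.26% for hepatocyte-like, 8.35% for endothelial-like, 20.1% for macrophage or monocyte-like, 5.002% for neutrophil-like, 8.05% for T cell-like and 6.88% for B cell-like cells, while unnamed clusters rose from 0.19% to 2.57%. Conventional dendritic cell-like cells were then named in neither tumour (0% and 0%).

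With at least 500 genes and at most 25% mitochondrial molecules, tumour 1 had 5.14% hepatocyte-like, 31.8% macrophage or monocyte-like, 4.52% neutrophil-like, 5.14% conventional dendritic cell-like, 15.6% T cell-like and 1.69% erythroid-like cells, with 5.21% in unnamed clusters. Tumour 2 had 11.0% stellate or fibroblast-like and 2.36% erythroid-like cells. With doublets kept, hepatocyte-like cells made up 5.55% and unnamed clusters 4.73% of tumour 1. At a resolution of 1.5, the share of hepatocyte-like cells in tumour 1 was 4.86% and that of unnamed clusters 5.37%, since part of the hepatocyte-like cells lost its name, and platelet or megakaryocyte-like cells made up 0.758%.

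With each cell named by its own marker score, tumour 1 had 7.14% hepatocyte-like, 12.4% endothelial-like, 24.8% macrophage or monocyte-like, 2.21% plasmacytoid dendritic cell-like, 10.9% T cell-like and 1.45% plasma cell-like cells. It had 2.97% cholangiocyte-like, 1.20% smooth muscle-like, 0.948% mesothelial-like, 2.21% NK cell-like, 0.253% mast cell or basophil-like and 2.27% platelet or megakaryocyte-like cells, which had 0 cells by cluster. Tumour 2 had 16.2% macrophage or monocyte-like and 2.82% T cell-like cells, and 7.75% cholangiocyte-like, 5.63% smooth muscle-like, 2.82% mesothelial-like, 13.4% plasma cell-like and 6.34% mast cell or basophil-like cells. Without the second clustering, no cell of either tumour was stellate or fibroblast-like (0% and 0%). Unnamed clusters then held 0.632% of tumour 1 and 69.0% of tumour 2, where 1.41% were macrophage or monocyte-like, 6.34% neutrophil-like and 0% conventional dendritic cell-like. A looser naming of clusters left 16.2% of tumour 2 unnamed and 12.7% cholangiocyte-like.

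Counts of genes in the planned comparisons stayed within a factor of 1.5 in 69 of 98 repeats on both tumours. With DESeq2 size factors, 5 genes were lower in erythroid-like and 74 in macrophage or monocyte-like cells. DESeq2's Wald test called 141 higher and 88 lower in macrophage or monocyte-like cells. Without the low-count filter, 1 gene was lower in erythroid-like, 15 in neutrophil-like and 141 in T cell-like cells. Without a filter on cells 5 were lower in erythroid-like cells, and 1 with doublets kept. With the strict filter on cells, 73 were lower in macrophage or monocyte-like and 375 in T cell-like cells, and erythroid-like cells had too few cells to be tested.

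Without the tumour as a block, 0 genes were lower in erythroid-like, 19 in neutrophil-like and 98 in T cell-like cells, and 133 were higher and 7 lower in macrophage or monocyte-like cells. In the wider fit, dropping the block left 6 genes lower in conventional dendritic cell-like, 6 in endothelial-like, 102 in hepatocyte-like, 9 in stellate or fibroblast-like cells and 9 in the unnamed clusters, and 30 higher in the latter against hepatocyte-like cells.

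With cells thinned to 1000 molecules, 1837 genes were tested in the planned comparisons. In erythroid-like cells, genes higher went from 185 to 122 and genes lower from 2 to 16. Genes lower went from 44 to 24 in macrophage or monocyte-like cells and from 41 to 94 in neutrophil-like cells, and lists from 26 to 11. In the wider fit, where all counts fell, thinning took the lists from 47 to 17. It left 61 genes higher and 4 lower in conventional dendritic cell-like, 153 and 6 in endothelial-like, 161 and 28 in hepatocyte-like, 53 and 3 in stellate or fibroblast-like cells, 60 and 1 in the unnamed clusters, and 19 and 63 in the latter against hepatocyte-like cells. Fewer molecules and fewer tested genes are part of that setting.

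Set in the wider fit, 513 genes were higher and 26 lower in macrophage or monocyte-like, 727 and 70 in neutrophil-like cells, and 423 higher in T cell-like cells. The repeats of the wider fit itself on both tumours kept 31 of 60 counts within the factor. With DESeq2 size factors, 21 genes were lower in stellate or fibroblast-like cells and 40 in the unnamed clusters. By the Wald test, 150 were higher in conventional dendritic cell-like cells, and 18 lower in stellate or fibroblast-like cells and 69 in the unnamed clusters. Without the low-count filter, 13 were lower in conventional dendritic cell-like cells, 996 genes higher and 15 lower in endothelial-like cells, 1606 higher in hepatocyte-like cells, and 19 lower in stellate or fibroblast-like cells and 8 in the unnamed clusters.

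Of the 26 list calls in the planned comparisons and the 47 in the wider fit, camera with an estimated correlation kept 0 and 7, and fry kept 3 and 21. With calls that camera did not make, fry had 4 and 23. A minimum of 20 cells per class and tumour left macrophage or monocyte-like cells alone, with no class to compare. Dropping the second clustering left erythroid-like and T cell-like cells, set against each other alone. Of 1976 genes, 93 were then higher and 38 lower in erythroid-like cells, and 38 higher and 93 lower in T cell-like cells. Each tumour alone gives a value with no test.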

Other observations

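The test of free RNA from the unnamed clusters, and the comparison of other classes of tumour 2 with the albumin-poor hepatocyte-like cells, were chosen only after the results were seen.

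Neutrophil-like cells of tumour 1 formed 2 clusters that differed in single genes and some lists, set side by side without a test. The chemokine list went both ways, with 3 members higher in the first and 2 lower of 5 (percentile 81.9). Genes of endoplasmic reticulum and oxidative stress stood higher in the first in 7 of 9 (median log2 ratio 0.98, percentile 99.6). Tumour-associated macrophage genes did so in 5 of 8 (median 0.92, percentile 99.3). The remaining lists lay at percentiles 12.4 to 94.9. The first, of 57 cells, had 8547 CPM of Ccl3 and 6648 CPM of Ccl4, attractants of monocytes and T cells, against 1578 and 1009 CPM in the second, of 75 cells. Hmox1 stood at 2219 against 109.9 CPM, the lysosomal protease Ctsb at 3158 against 609 CPM and Cd63 at 726 against 79.9 CPM. The second had more Ccl6 (3816 against 470 CPM), Slc16a3 (1189 against 341 CPM) and Lmnb1 (3216 against 875 CPM). Mitochondrial molecules had medians of 19.8% in the first and 4.08% in the second. The genes were chosen after the values were seen.

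Transcripts typical of the unnamed clusters were present in other classes of tumour 2. In all 40 T cell-like, neutrophil-like and erythroid-like cells of tumour 2, or 100% (from 91.2%), Clu was present, against 139 of 449 in tumour 1. Their median depths differed, at 3076 and 1588 molecules per cell. Presence in all cells argues against doublets as the only source, since these would touch a minority of cells. It does not show that no doublets were among them. Free RNA from the unnamed clusters stays open. Of pairs of 25 genes and 3 classes, 77.3% lay within a factor of 2 of the class's median ratio. That ratio was 9.80%, 11.5% and 15.4% of the level in the unnamed clusters for T cell-like, neutrophil-like and erythroid-like cells. The 25 genes were picked by the highest ratio of the unnamed clusters to a pool of other classes, these 3 included. That choice narrows the ratios in advance, so the share cannot decide. No biological explanation was tested, as the 2 tumours belong to 1 group.

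The Ras output and growth factor genes of the unnamed clusters have doublets and dissociation among their technical explanations. Hepatocyte and fibroblast markers stood at medians of 2.76% and 2.07% of their level in their own classes. Low levels were partly set in advance, since these clusters went unnamed for want of such markers. The values show only that the cells left unnamed lack transcripts that doublets of these classes would carry. The list of dissociation stress genes had a camera adjusted p of 0.716, with a median log2 difference of 0.30. No other technical explanation and no biological one was tested for these genes.

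Cell cycle genes were present in neutrophil-like cells of tumour 2, with a summed level of 2791 CPM against 92.9 CPM in tumour 1. In T cell-like and erythroid-like cells of tumour 2 the sum was 888 and 860 CPM, at most 31.8% of that, which argues against free RNA of cycling cells. The makeup of the class could account for the difference. Without 1 cluster of 9 cells rich in granule proteins, which had 3368 CPM, the sum was 253 CPM, or 9.06%. No biological explanation was tested.

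A hypothesis was that the albumin-poor part of the hepatocyte-like cells of tumour 1 shares the profile of the unnamed clusters of tumour 2. Over 144 list genes, the log2 ratio between the parts in tumour 1 and that between the unnamed clusters and hepatocyte-like cells in tumour 2 had a Spearman correlation of 0.663, and 117 genes had the same sign. In place of the unnamed clusters, other classes of tumour 2 gave 0.341 to 0.519, and over 125 genes outside the liver lists the unnamed clusters gave 0.591 and the others 0.232 to 0.430. Since classes of other kinds gave part of the correlation, and 1 passed the same threshold of 0.5, the test does not decide. Hmga2 stood at 29.7 CPM in the albumin-poor part, against 1625 CPM in the unnamed clusters of tumour 2, and the albumin-poor part also had more mitochondrial molecules and all 21 stress genes higher. A state of damaged cells stays open too, though without the stress genes the correlation was no lower, at 0.680 over 123 genes.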
